A study of Homo sapiens with 4 samples.

How the data were processed

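The study measured RNA bound to beta-catenin, the transcriptional co-activator of Wnt signalling, in 2 human colon adenocarcinoma cell lines, HT-29 and CaCo-2. In RNA immunoprecipitation followed by sequencing (RIP-Seq), a protein is pulled down from a lysate with an antibody and the RNA that comes with it is sequenced. Per the labels, nuclei were lysed, RNA-protein complexes were collected with a beta-catenin antibody and protein G beads, and libraries were made with a TruSeq RNA kit. Each line had 1 RIP library and 1 input library without antibody, so there were 4 libraries and 1 library per group. A mock precipitation with an unrelated antibody was not analysed here. The submitters' processing notes name CASAVA 1.4, Bowtie2, TopHat2 2.0.8, Cufflinks and Cuffdiff with the hg19 build; versions of the other tools and the strandedness of the libraries are not given in the sources used here.

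For each line the authors deposited a Cuffdiff table with 1 row per Ensembl transcript. Expression is in FPKM per the labels' tools, that is, fragments scaled by transcript length and by library size, and was normalised by the authors. The deposited p-values and q-values are the authors' own Cuffdiff results from 1 library per side, and they are quoted as such. Coordinates are those of hg19 in the deposited tables, written from 1. The number of columns of per-sample values left unmapped was 0.

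The tables hold part of each library. In HT-29, the lowest deposited fold between RIP and input was 1.5 and the lowest RIP FPKM was 1.31. In CaCo-2, the lowest deposited fold was 1.5 and the lowest RIP FPKM 0.842. All 9880 transcripts of HT-29 and all 11943 of CaCo-2 had the status OK. Transcripts lower in the RIP, or changed by a smaller fold, were not analysed here. For this reason, planned counts of transcripts lower in the RIP, centring on the median ratio, rescaling to a fixed total and a limma test of RIP against input across the lines were not run: the selection of transcripts fixes the sign of every ratio. Nor can a share of listed transcripts be read as an enrichment among all expressed transcripts.

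The ratio used here was log2 of RIP FPKM plus 1 over input FPKM plus 1, with a pseudocount of 1 FPKM, which understates the ratio of low transcripts. Transcripts with at least 1 FPKM in at least 1 of the 2 libraries of a line were kept, and those with a ratio of at least 2-fold were counted. Where the input is listed at 0, no fold is given. Some RIP levels are given without their input level, which can then be 0. With 1 library per group there is no replicate error and no test of a transcript was made. Shares carry 95% Wilson intervals, which cover counting error only. Sequencing depth is unknown from these tables.

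lncRNAs were the transcripts of the classes lincRNA, antisense, sense_intronic and sense_overlapping. The 26 gene lists were fixed before the data were examined. Each was summarised by 1 transcript per gene, the one with the highest RIP FPKM, and its median log2 ratio was placed among 10000 random lists of equal size drawn within 10 bins of mean expression from the same table. A percentile therefore compares a list with other listed genes, not with all genes. The transcript so chosen can differ between the lines, for example for BMP4, DVL2, LRP6, DANCR, JPX, RPSA, ATP5B, SNRNP70, SERPINA1 and FOS. After the data were seen, percentiles were also taken with at least 1 FPKM in both libraries, for the list and the random lists alike; they are given beside each printed percentile that moved by over 1.5 times, and for some other lists. Simulated lists of 20 random genes were drawn from the HT-29 table (6489 genes) after its ratios were shuffled across genes. Of these, 10% of unchanged lists fell outside the 5th to 95th percentile and 100% of lists raised by 1 log2 unit passed the 95th. The shuffle removes any link between ratio and expression, so the first share does not test the matching. Most lists here hold fewer genes, to which the second share does not carry over. The shared count between lines was set against the product expected by chance and against 10000 shuffles within expression bins, among transcripts that passed the filter in both tables. Correlations were taken across transcripts, which are not independent replicates.

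Genes were named by a rule fixed before the data were examined: CTNNB1, RBM5-AS1, RBM5 and RBM6; per line the 10 highest ratios outside small RNAs; the 10 highest by the lower ratio of the 2 lines; the 5 highest lncRNAs per line and over both lines; and up to 4 members per list. Sex-linked marker genes were left out. A gene named outside this rule is said to be so. The parts of the rule for the lowest ratios have no members. The tables' gene names gave 5423 matches of 6489 names in HT-29 and 6066 of 7452 in CaCo-2 to current symbols of the RefSeq annotation of GRCh38.p14, used for names alone. Date-like names, 22 in HT-29 and 28 in CaCo-2, were not named.

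For short RNAs the FPKM at a given length was compared with the smallest value that recurred in at least 2 transcripts of that length, within 0.3%, and interpolated on a log scale between such lengths. Values within 0.05 of a whole multiple were called whole, and the count was repeated without the RNAs that set the smallest value at their length. On simulated short RNAs the multiple was recovered in 100% of cases. These were whole multiples of a smooth curve without noise, so this checks the calculation alone. Alternatives were a pseudocount of 0.1 FPKM, other FPKM filters, a 3-fold threshold, the authors' q-values at 0.05, leaving out small RNAs and a rank correlation. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; plots used matplotlib 3.10.9.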

Results

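The data cover 2 colon adenocarcinoma lines, HT-29 and CaCo-2, each with 1 input library of nuclear RNA and 1 beta-catenin RIP library. The question was which long non-coding RNAs associate with beta-catenin in the nucleus of these lines. The tables list 9880 transcripts of 6489 gene names for HT-29 and 11943 transcripts of 7452 gene names for CaCo-2, all at least 1.5-fold higher in the RIP as deposited. Input was listed at 0 for 3137 transcripts (31.8%) in HT-29 and for 3466 (29.0%) in CaCo-2. A value given below under a gene name is that of 1 listed transcript. Transcripts of the same gene that are not listed were not analysed here. An input at or near 0 therefore does not show that the gene is absent from the input. There were no replicates, so the values below carry no error between libraries, and no fold given here was tested.

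In HT-29, the RIP was at least 2-fold above input for 5529 of 9880 transcripts (56.0%), which belong to 4185 gene names. A transcript listed at 0 in input reaches this ratio by construction once it passes the filter of 1 FPKM. Of the 5529, 3137 were such transcripts, and the count without them, an alternative chosen after seeing the data, was 2392. The authors' deposited table gives q at or below 0.05 for 304 transcripts. Outside small RNAs, the highest ratios included transcripts classed as processed transcript, retained intron, pseudogene, protein-coding and lincRNA. A processed transcript of RBPMS, an RNA-binding protein, was listed at 0 FPKM in input and 754 in the RIP. That value equals, within 0.3%, the smallest FPKM that recurs among short RNAs of 98 nucleotides in this library. The transcript spans 76890 nucleotides of the genome and its length without introns was not analysed here, so the match does not give its number of fragments. Its q was 0.725 in the authors' deposited table. RPS4X and RPL8, which encode ribosomal proteins, reached 91.5 and 82.4 FPKM in the RIP against 0 and 0.0644 in input. TPT1 reached 42.2 and ANKRD10 40.7, both from an input listed at 0, with q of 0.628 and 0.789 in the authors' deposited table. A short RNA of 128 nucleotides was at 407 FPKM, 10 times the smallest for its length, so ANKRD10 lay near that smallest value. The length of ANKRD10 without introns was not analysed here, so this does not give its number of fragments. The list also held EIF4A1P12, a processed pseudogene, at 38.9 FPKM from an input listed at 0, and MALAT1, a nuclear speckle lncRNA, at 83.0 against 1.18. In the authors' deposited table q was 0.289 for RPS4X and 0.949 for RPL8.

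In CaCo-2, 4129 of 10116 transcripts that passed the filter (40.8%) were at least 2-fold higher in the RIP, from 3298 gene names. Input was listed at 0 for 2679 of them, which leaves 1450 in the same alternative chosen after seeing the data. The authors' deposited table gives q at or below 0.05 for 268 transcripts, 249 of which passed the filter. MALAT1 led the transcripts outside the small RNA classes, with 128 FPKM in the RIP and an input listed at 0. KLHL22-IT1 followed at 101 and TANGO2 at 25.4, both also from 0. KLHL22-IT1 spans 109 nucleotides and its value is the smallest that recurs among short RNAs of that length. AC069200.1, a pseudogene that spans 125 nucleotides, was also at 25.4 FPKM in the RIP with input listed at 0. That is 0.999 times the smallest FPKM interpolated for its length, so TANGO2 lay near that smallest value too. The length of TANGO2 without introns was not analysed here, so its number of fragments is unknown. RPL8 was at 34.5 FPKM against 0.678 in input, and ALYREF, an mRNA export factor, at 19.5 against 0.00112. The q in the authors' deposited table was 1 for MALAT1, RPL8 and ALYREF and 0.856 for KLHL22-IT1 and TANGO2.

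Long non-coding RNAs made up 462 of the 9880 listed transcripts in HT-29 (4.68%, 95% Wilson interval 4.28 to 5.11) and 692 of the 11943 in CaCo-2 (5.79%, 5.39 to 6.23). In HT-29 they comprised 160 lincRNA, 266 antisense, 31 sense-intronic and 5 sense-overlapping transcripts. In CaCo-2 the numbers were 237, 376, 67 and 12. At least 2-fold higher in the RIP were 208 of 462 in HT-29 (45.0%, 40.5 to 49.6) and 167 of the 541 that passed the filter in CaCo-2 (30.9%, 27.1 to 34.9). Protein-coding transcripts passed the same threshold at 53.2% (51.8 to 54.6) in HT-29 and 42.0% (40.6 to 43.4) in CaCo-2. Input was listed at 0 for 117 of the 208 and 110 of the 167 lncRNA transcripts. The following shares were added after seeing the data. Without transcripts at input 0, lncRNAs passed in 91 of 345 cases in HT-29 (26.4%) and 57 of 431 in CaCo-2 (13.2%), against 35.5% and 23.2% of protein-coding transcripts. With at least 1 FPKM in both libraries, 39 of 157 (24.8%, 18.7 to 32.1) and 20 of 141 (14.2%, 9.37 to 20.9) passed, against 22.7% (21.0 to 24.6) and 14.2% (12.4 to 16.2) of protein-coding transcripts. In the authors' deposited table, q at or below 0.05 was reached by 2 lncRNA transcripts in each line. These were SCARNA2 and PAX8-AS1 in HT-29, and SCARNA2 and LINC00273 in CaCo-2. PAX8-AS1 (chromosome 2, 113993117 to 114024581) and LINC00273 (chromosome 16, 33961052 to 33962503) were named after their values were seen. PAX8-AS1 was at 3.95 FPKM in the RIP with input listed at 0, and LINC00273 at 8.84 against 4.48.

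The lncRNAs with the highest ratio in HT-29 were SNORA71B, SCARNA2, MALAT1, PTCHD3P1 and AC069257.8, and in CaCo-2 MALAT1, SCARNA2, SNORD3A, RP11-230C9.3 and SLC8A1-AS1. SNORA71B is a small nucleolar RNA annotated as lincRNA (ENST00000439232, chromosome 20, 37053843 to 37053978). It was at 1480 FPKM in the HT-29 RIP with input listed at 0 and q of 0.0728 in the authors' deposited table. An overlapping SNORA71B entry of class snoRNA (ENST00000364546, 37053846 to 37053979) was listed in CaCo-2 at 101 against 66.0 FPKM, a log2 ratio of 0.61. How reads were shared between these entries was not analysed here. In the CaCo-2 RIP, a lincRNA transcript named SNORD3A (ENST00000584923, spanning 699 nucleotides) was at 31.7 FPKM, SLC8A1-AS1 at 12.2 and RP11-230C9.3 at 19.4, each from an input listed at 0. RP11-230C9.3 spans 129 nucleotides and was at 0.995 times the smallest FPKM for that length. SNORD3A matched, within 0.3%, a short RNA of 122 nucleotides at about the smallest FPKM for its length. A short RNA of 137 nucleotides was at 24.5 FPKM, 1.99 times the smallest for its length, so SLC8A1-AS1 lay near that smallest value too. Lengths of SNORD3A and SLC8A1-AS1 without introns were not analysed here, so their number of fragments is unknown. The q of SNORD3A, SLC8A1-AS1 and RP11-230C9.3 was 0.907, 0.856 and 0.925 in the authors' deposited table.

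Across both lines, 82 lncRNA transcripts were listed in both tables, and 15 were at least 2-fold higher in the RIP of both. SCARNA2, a small Cajal body RNA annotated as lincRNA (ENST00000602755, chromosome 1, 109642815 to 109643241), had input listed at 0 in both lines. Its RIP level was 106 FPKM in HT-29 and 53.3 in CaCo-2, with q of 0.000259 and 3.14e-08 in the authors' deposited table. Within the classes counted here as lncRNA, no other transcript had q at or below 0.05 in both lines in that table. A transcript of ANKRD30BL (ENST00000470729), of the class processed transcript, is outside these classes and was named after its values were seen. It was at 309 against 91.6 FPKM in HT-29 and 296 against 116 in CaCo-2. Its q was 2.8e-08 and 1.83e-05 in the authors' deposited table. A short MALAT1 isoform (ENST00000508832, chromosome 11, 65269807 to 65271080) was at 83.0 against 1.18 FPKM in HT-29 and at 128 against 0 in CaCo-2, with q that rounds to 1 in both lines in the authors' deposited table. PTCHD3P1 (chromosome 10, 29698520 to 29756207) was at 20.6 FPKM in the HT-29 RIP and 2.79 in the CaCo-2 RIP, both from an input of 0. GAS5, a host gene of small nucleolar RNAs (ENST00000449289, chromosome 1, 173833038 to 173837127), was at 6.67 against 1.46 in HT-29 and at 4.17 against 0 in CaCo-2. CTD-2651B20.6, a sense-intronic transcript (chromosome 15, 45492523 to 45492830), had similar ratios in the 2 lines, 10.4 against 2.91 FPKM in HT-29 and 16.8 against 4.96 in CaCo-2. Its deposited fold was 3.57 and 3.39, with q of 0.667 and 0.638 in the authors' deposited table. With at least 1 FPKM in both libraries of each line, 4 lncRNA transcripts were at 2-fold or more in both: CTD-2651B20.6, AC004702.2, RP11-805J14.5 and RP11-746M1.1, the last 3 named after their values were seen. SCARNA2, MALAT1, PTCHD3P1 and GAS5 are not among them, since input was listed at 0 in at least 1 line.

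**Figure D1:**
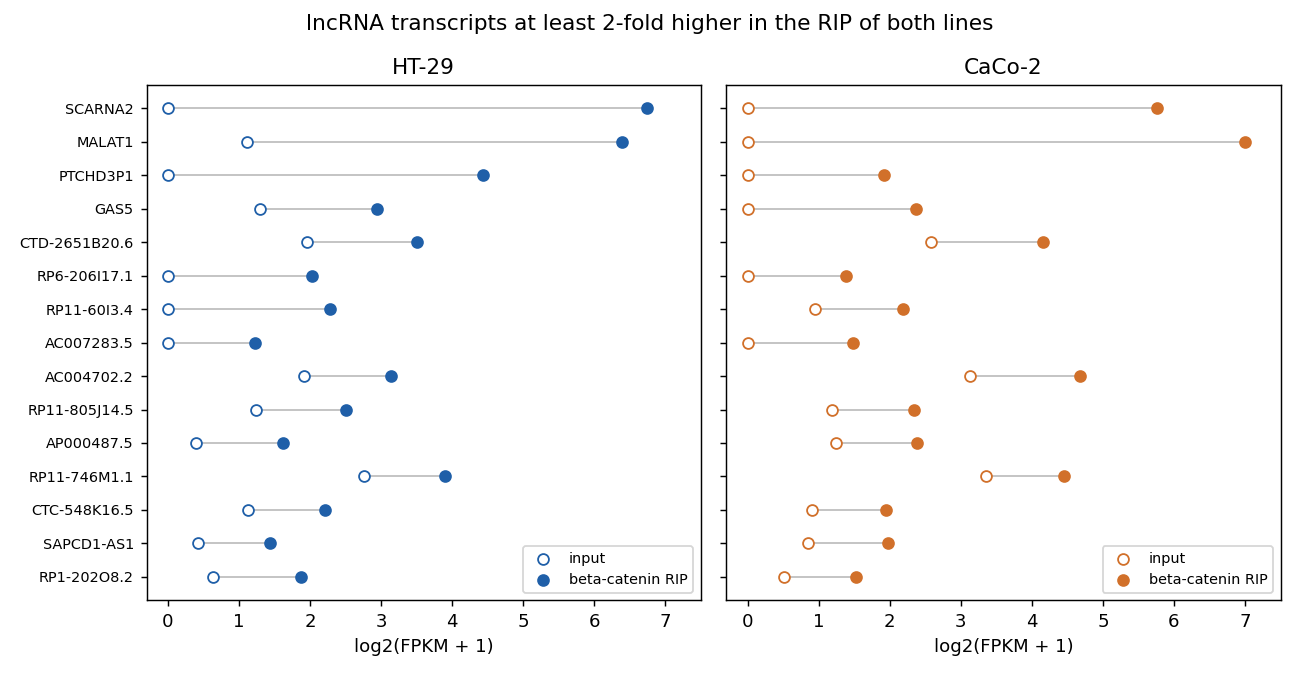
The 15 lncRNA transcripts at least 2-fold higher in the RIP of both lines, with log2(FPKM + 1) on the horizontal axis; open points are input and filled points the beta-catenin RIP, with 1 library each. SCARNA2 moves from 0 in input to 106 FPKM in HT-29 and 53.3 in CaCo-2. Transcripts are ordered by the lower of their 2 log2 ratios, highest at the top.

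LUST (RBM5-AS1), the lncRNA of the series title, was not analysed here: the number of its transcripts among those listed was 0 in both lines. Of its neighbours on chromosome 3, RBM6, an RNA-binding protein, was listed by the same retained-intron transcript (49977530 to 50000460) at 1.74 against 0.518 FPKM in HT-29 and 2.29 against 1.07 in CaCo-2. A nonsense-mediated-decay transcript of RBM6 (49977584 to 50095286) was also listed in CaCo-2, at 1.83 against 0.480, a log2 ratio of 0.94. RBM5 was listed in CaCo-2 by a retained-intron transcript (50150795 to 50151675) at 2.32 against 1.25, a log2 ratio of 0.56, and by a nonsense-mediated-decay transcript (50126388 to 50137443) at 0.940 against 0, below the filter. The locus list of these genes was at the 43.6th and 28.5th percentile of random lists. Set against lists with at least 1 FPKM in both libraries, a comparison added after seeing the data here and below, its 2 genes in CaCo-2 were at the 70.005th. CTNNB1, which encodes beta-catenin, was listed by ENST00000396185 in HT-29 (41240996 to 41281934) at 11.8 against 7.69 FPKM, a log2 ratio of 0.56. In CaCo-2 the isoform with the highest RIP level, ENST00000396183, was at 3.56 against 2.32, a log2 ratio of 0.46. A shorter protein-coding isoform there, ENST00000441708 (41263577 to 41266503), was at 2.17 against 0.311, a log2 ratio of 1.27, and a retained-intron transcript was at 0.896 against 0.438. The q in the authors' deposited table was 0.622 in HT-29 and 0.899, 0.971 and 1 in CaCo-2.

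Wnt pathway genes were listed in both lines, mostly at a few FPKM, and how their ratios differ between lines was not tested. Of the Wnt target genes, 9 were listed in HT-29 and 7 in CaCo-2, and 3 and 4 passed 2-fold, with medians at the 38.3rd and 85.9th percentile of random lists. In CaCo-2, 4 were left with at least 1 FPKM in both libraries, at the 20.2nd percentile of lists under the same filter. RNF43, a negative regulator of Wnt receptors, was at 14.2 against 6.88 FPKM in HT-29 and 8.77 against 2.48 in CaCo-2. BMP4 was at 5.32 against 0 and 2.46 against 0.247, TCF7 at 4.23 against 0 and 2.48 against 0.703, and TDGF1 was listed in HT-29 at 2.67 against 0. Of the pathway and beta-catenin complex components, 13 were listed in HT-29, with 10 past 2-fold and a median at the 95.9th percentile, or the 77.3rd over the 6 with at least 1 FPKM in both libraries. In CaCo-2, 20 passed the filter, 6 were past 2-fold, and the median was at the 30.2nd percentile; with at least 1 FPKM in both libraries, 0 of 10 were past 2-fold, at the 8.95th. APC, the scaffold of the destruction complex, was listed in HT-29 at 2.13 against 0 FPKM, and CREBBP at 3.69 against 0. DVL2 was at 2.77 and 2.22 FPKM in the 2 RIPs, and LRP6 at 1.65 and 1.30. In the authors' deposited table, 2 component transcripts of CaCo-2 had q at or below 0.05 and were named after their values were seen. BTRC, the ubiquitin ligase subunit that recognises beta-catenin (chromosome 10, 103113864 to 103317078), was at 2.75 against 0.808 FPKM with q of 0.0298. A protein-coding DVL2 isoform (chromosome 17, 7128774 to 7137637) was at 1.21 against 0 with q of 0.0237. The same isoform had q of 0.9998 in HT-29 in the authors' deposited table. The Wnt-related antisense and locus lncRNAs had 1 member listed per line, PVT1, at the 34.3rd and 81.2nd percentile.

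Among fixed lncRNA lists, 10 cancer-associated lncRNA genes passed the filter in each line, with 5 and 4 past 2-fold and medians at the 28.6th and 45.0th percentile for HT-29 and CaCo-2. CRNDE was at 4.67 FPKM in the HT-29 RIP, UCA1 at 1.68 and LINC00467 at 1.32 in CaCo-2. DANCR was at 15.2 against 5.16 in HT-29 and 7.11 against 1.84 in CaCo-2. Of the chromatin- or speckle-retained lncRNAs, 5 were listed per line, at the 47.4th and 22.2nd percentile. With at least 1 FPKM in both libraries, 2 were left in HT-29, at the 99.7th, and 1 in CaCo-2, at the 48.6th; of the 2, MALAT1 alone passed 2-fold, so the first value rests on it. Beside MALAT1 they included TUG1 in HT-29 at 2.72 against 0.846 FPKM and JPX, at 1.92 against 0 in HT-29 and 1.28 against 0.464 in CaCo-2. Of the snoRNA host genes, 15 and 9 were listed, at the 44.1st and 17.1st percentile (69.7th over 12 genes in HT-29 with at least 1 FPKM in both libraries), among them ZFAS1 at 15.9 against 5.81 FPKM and SNHG15 at 4.78 against 0 in HT-29.

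Of snoRNA genes, 86 were listed in HT-29, 82 of them past 2-fold, and in CaCo-2 34 and 25, with both medians at the 100th percentile. Many of these ratios come from an input of 0, which held for 31 and 16 genes. Under a minimum of 1 FPKM in both libraries, 51 of 55 genes passed 2-fold in HT-29 and 9 of 18 in CaCo-2. Their medians were 2.49 and 1.13, against 3.67 and 2.68 for all, and lay at the 100th and 99.6th percentile of lists under the same filter. C/D snoRNAs with input above 0 had a median fold of 2.55 over 10 transcripts in HT-29 and 1.87 over 5 in CaCo-2, where the median of all such transcripts of the table was 2.46 and 2.21. The abundant structured RNAs numbered 13 in HT-29, with 10 past 2-fold and a median at the 99.4th percentile, against 3 in CaCo-2, with 1 past 2-fold and a median at the 36.7th percentile. RNU4-2, the U4 spliceosomal RNA (chromosome 12, 120729566 to 120729706), was at 101301 against 15941 FPKM in HT-29, with q of 5.53e-11 in the authors' deposited table. RNY4 was at 27329 against 2128 in HT-29, with q of 0.129 in the authors' deposited table. RNY5 was listed at 0 in input and at 15787 FPKM in the HT-29 RIP and 6628 in the CaCo-2 RIP. The q of RNY5 was 0.435 and 0.637 in that table. RNY5 was not set against a smallest recurring FPKM, so these values can rest on few fragments. The H/ACA snoRNAs, guides of pseudouridylation, and the scaRNAs together had 66 transcripts listed in HT-29 and 23 in CaCo-2. Where input was above 0, their median fold was 6.54 over 46 transcripts in HT-29 (quartiles 2.99 and 12.0) and 2.59 over 13 in CaCo-2 (1.82 and 3.51). Named after their values were seen, SNORA71A (chromosome 20, 37055952 to 37056085) was at 6200 against 817 FPKM in HT-29 and SNORA71C (37058313 to 37058446) at 4405 against 321, with q of 8.01e-05 and 0.00185 in the authors' deposited table. The microRNA genes numbered 8 in HT-29 and 17 in CaCo-2, all but 2 and 4 from an input of 0 and with both medians at the 100th percentile. MIR150 was at 3298 FPKM in the HT-29 RIP, 1.01 times the smallest FPKM for its length. MIRLET7I was at 1698 in the CaCo-2 RIP, with q of 0.856 in the authors' deposited table. It was not set against a smallest recurring FPKM, so its value too can rest on few fragments. With at least 1 FPKM in both libraries, 1 microRNA gene was left in HT-29 and 3 in CaCo-2, and the medians went from 8.83 to 0.70 and from 8.45 to 1.28, at the 37.1st and 90.2nd percentile. Of the 10 symbols in the fixed list of ribosomal RNA genes, 2 were listed in HT-29, with RNA5S9 at 14217 against 5124 FPKM and a median at the 34.9th percentile, and 0 in CaCo-2; RNA5S9 alone had at least 1 FPKM in both libraries, at the 67.4th. By name, 5S rRNA genes and their copies had 24 transcripts listed in HT-29 and 11 in CaCo-2, 7 and 2 of them with input above 0. In 86 of 91 HT-29 short RNAs and 118 of 120 in CaCo-2 with at most 10 times the smallest FPKM recurring at their length, the RIP value was a whole multiple of it, within 0.05. Without the RNAs that set this smallest value, which are whole by construction, 48 of 53 and 46 of 48 were, where 10% would be by chance.

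**Figure D2:**
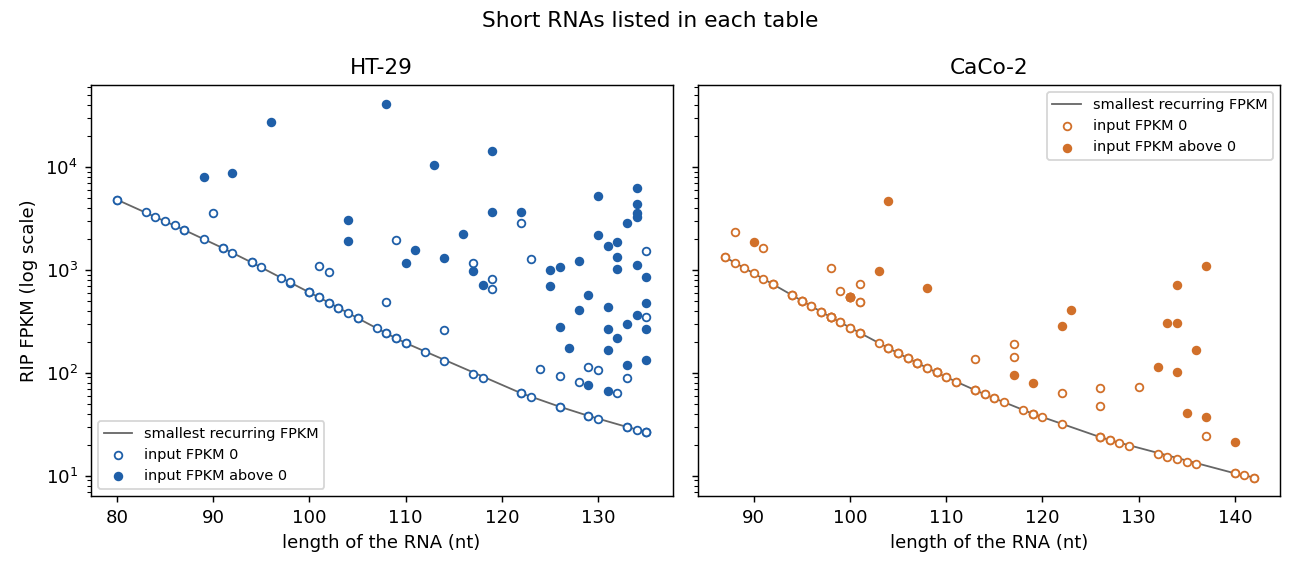
RIP FPKM on a log axis against RNA length in nucleotides for short RNAs listed in HT-29 (left) and CaCo-2 (right); open points have an input FPKM of 0, filled points an input above 0, and the line joins the smallest FPKM that recurs at each length. Of the open points, 55 of 75 in HT-29 and 89 of 108 in CaCo-2 lie on the line, which is drawn through points that recur; without the RNAs that set it, 17 of 37 and 17 of 36 do.

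Histone genes were listed mostly in HT-29. There, 21 replication-dependent histone genes were listed, 11 past 2-fold, and 10 had q at or below 0.05 in the authors' deposited table; in CaCo-2, 2 passed the filter and 0 had such a q. The list, drawn by name, held pseudogenes; without them, an alternative chosen after seeing the data, 20 genes remained in HT-29, with 10 past 2-fold and 9 with such a q, and 1 in CaCo-2. HIST3H2A (chromosome 1, 228645065 to 228645560) was at 116 against 12.9 FPKM in HT-29, with q of 0 in the authors' deposited table, and HIST1H4I at 27.7 against 0.683, with q of 0.00154. The list's median was at the 86.0th percentile in HT-29 and the 61.2nd in CaCo-2, and in HT-29 at the 34.8th over the 17 genes with at least 1 FPKM in both libraries. The difference between the lines was not tested.

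**Figure D3:**
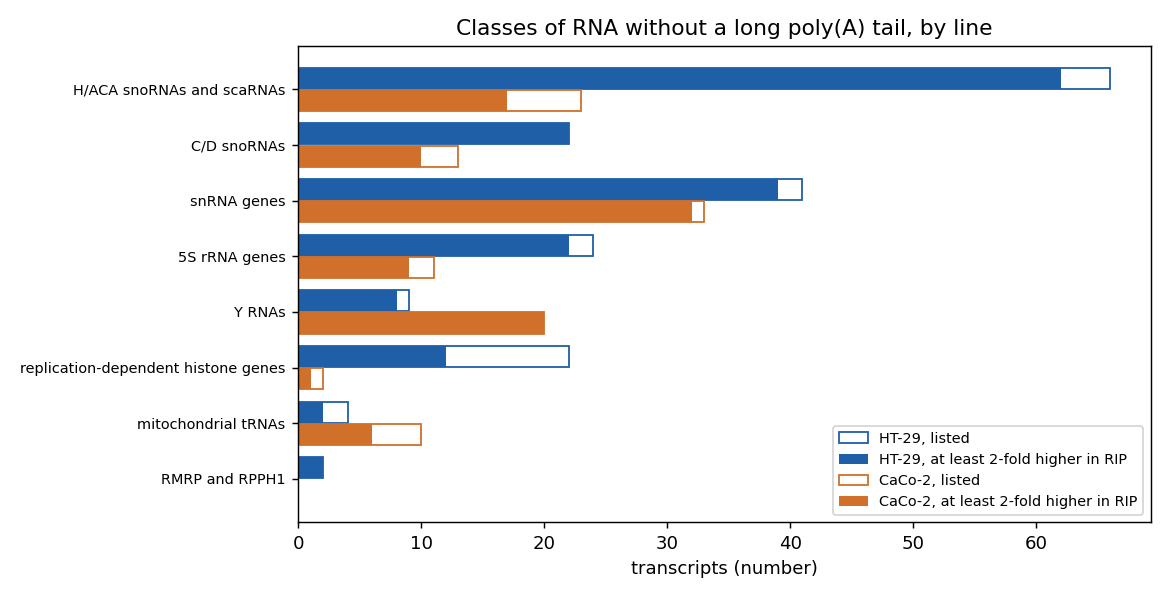
Number of listed transcripts in classes of RNA without a long poly(A) tail, in HT-29 (blue) and CaCo-2 (orange); the full bar counts listed transcripts and its filled part those at least 2-fold higher in the RIP. H/ACA snoRNAs and scaRNAs number 66 in HT-29 and 23 in CaCo-2, and histone transcripts, pseudogenes included, 22 and 2 among those past the filter. The class of 7SL and 7SK, the largest in both lines with 101 and 96 listed transcripts, is not drawn.

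Cytosolic ribosomal protein genes stood above random lists in both lines. Of these genes, 44 of 70 passed 2-fold in HT-29 and 25 of 53 in CaCo-2, with medians of 1.18 and 0.97 at the 100th and 99.9th percentile. Under a minimum of 1 FPKM in both libraries, 33 of 63 and 13 of 31 passed, with medians at the 99.9th percentile in both lines. RPSA was at 21.9 FPKM in HT-29 (ENST00000478027) and 12.1 in CaCo-2 (ENST00000443003), both against 0, and RPL6 at 10.4 against 0 in HT-29. The RPSA transcript of CaCo-2 was at 11.3 against 0 in HT-29. Of nuclear-encoded respiratory chain genes, 32 of 51 and 27 of 45 passed 2-fold, with medians of 1.29 and 1.15 at the 99.8th and 99.9th percentile. Input was listed at 0 for 15 and 18 of them; with at least 1 FPKM in both libraries, 8 of 24 and 4 of 16 passed, and the medians were 0.79 and 0.80, at the 50.5th and 93.2nd percentile. ATP5B, a subunit of ATP synthase, was at 13.8 and 3.02 FPKM and NDUFA13, of complex I, at 7.51 and 4.06. Splicing factor genes passed 2-fold in 19 of 30 and 17 of 29 cases, at the 96.3rd and 98.7th percentile, and with at least 1 FPKM in both libraries in 7 of 19 and 2 of 14, at the 68.3rd and 55.1st. SNRNP70 was at 10.2 against 0.339 FPKM in HT-29 and 7.55 against 2.37 in CaCo-2, and HNRNPD at 3.24 against 0 and 5.80 against 0.168. Mitochondrially encoded genes were 4 and 10 transfer RNAs, at the 58.9th and 95.03rd percentile. MT-TS1 had a deposited fold of 10.2 in HT-29 and 6.19 in CaCo-2, with q of 0.0339 and 3.7e-09 in the authors' deposited table. Housekeeping genes, 15 per line, were at the 49.8th and 97.3rd percentile, with YWHAZ at 13.8 and 4.47 FPKM in the RIPs, both against 0.

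The lists of cell identity had few members. Intestinal epithelial genes numbered 11 and 9, at the 82.7th and 45.5th percentile, and 8 and 6 with at least 1 FPKM in both libraries, at the 33.7th and 30.6th, with KRT18 at 54.3 against 14.7 FPKM in HT-29 and 32.0 against 11.6 in CaCo-2. Hepatic-type genes numbered 1 and 9, at the 92.3rd and 41.0th percentile. ALB was at 10.7 against 0.0983 FPKM in CaCo-2, and SERPINA1 at 4.68 and 3.39 in the 2 RIPs. Stem cell and tumour-initiating cell markers numbered 9 and 7, at the 64.5th and 72.1st percentile, and under the same minimum 5 and 3, at the 90.7th and 35.5th, with ITGA6 at 9.07 against 0.760 FPKM in HT-29 and ALDH1A1 at 7.75 against 0 in CaCo-2. Secretory-pathway and membrane protein genes numbered 14 and 15, with 12 and 3 past 2-fold, at the 94.5th and 81.4th percentile. CALR, of the endoplasmic reticulum, was at 4.74 against 0.228 FPKM in HT-29. Immediate early genes numbered 2 and 4, at the 65.9th and 35.0th percentile, and under that minimum 1 and 2, at the 30.6th and 58.9th, with FOS at 2.89 against 0 in HT-29 and 7.08 against 3.77 in CaCo-2. Of markers of other cell types, fibroblast genes numbered 0 in both lines, haematopoietic genes 0 and 2, neural genes 3 and 1, and endothelial genes 2 and 0. The highest of these were MBP at 3.77 FPKM in HT-29 and CD74 at 1.89 in CaCo-2.

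Between the lines, 1928 transcripts were listed in both tables, 19.5% of the HT-29 table and 16.1% of the CaCo-2 table. By gene name, 3843 were shared, and 1721 of these shared a transcript (44.8%). Of 1784 transcripts that passed the filter in both, 1026 were at least 2-fold higher in the HT-29 RIP, 761 in the CaCo-2 RIP and 535 in both. Chance gives 438 from the product of the shares, and shuffling within expression bins gave 469 on average, between 431 and 505. Of the transcripts listed in both tables, 226 had input at 0 in both. Among the 1072 with input above 0 in both lines, an alternative chosen after seeing the data, 144 were shared, against 103 from the product and between 81 and 135 from shuffling. Where all 4 libraries had at least 1 FPKM, 47 of 370 were shared, against 27.5 from the product and between 26 and 53 from shuffling. The log2 ratios of the 1784 transcripts correlated across transcripts with Pearson r = 0.52 and Spearman rho = 0.32, and r was 0.41 with at least 1 FPKM in all 4 libraries. Without small RNAs, r was 0.36 over 1719 transcripts. Among the 1136 with input above 0 in both lines, the deposited log2 fold changes gave r = 0.30 and rho = 0.15.

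Outside small RNAs, the 10 transcripts with the highest lower ratio of the 2 lines belonged to MALAT1, RPL8, ALYREF, CYBA, RPSA, ACTB, STT3A, PTPN4, GRINA and PDCD5. CYBA, a subunit of the NADPH oxidase, was at 32.4 FPKM in the HT-29 RIP and 12.8 in the CaCo-2 RIP, against 0 and 0.0128 in input. A processed transcript of ACTB was at 15.7 and 7.24, STT3A at 6.58 and 7.47, and PDCD5 at 5.69 and 5.47 FPKM in the RIPs. Input was listed at 0 in both lines for these 3 transcripts. PTPN4 was at 5.93 against 0 in HT-29 and 5.61 against 0.00219 in CaCo-2. GRINA was at 5.55 in HT-29 and 10.1 in CaCo-2, both from an input listed at 0, with q of 0.402 and 0.0204 in the authors' deposited table. That table gives q at or below 0.05 in both lines for 19 transcripts, 9 of them from an input of 0 in both. Of the 304 such transcripts of HT-29, 67 were listed at all in CaCo-2, and of the 268 of CaCo-2, 66 were listed in HT-29.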

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

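The alternatives that left out transcripts at input 0, set 1 RIP minimum (1.31 FPKM) for both tables, took 1 transcript per gene name or left pseudogenes out of the histone list were chosen after seeing the data, as were percentiles of lists and shares by class under another filter. In each group of 6 values that follows, the order is transcripts at least 2-fold higher in HT-29, in CaCo-2 and in both lines, then lncRNA transcripts in HT-29, in CaCo-2 and in both; as reported they are 5529, 4129, 535, 208, 167 and 15. With at least 1 FPKM in both libraries they were 863, 338, 47, 39, 20 and 4, and with at least 5 FPKM in at least 1 library 1163, 472, 89, 37, 20 and 5. At 3-fold they were 2332, 1102, 136, 60, 26 and 4. With the authors' q at or below 0.05 in place of the fold they were 304, 249, 19, 2, 2 and 1. Without transcripts at input 0 they were 2392, 1450, 144, 91, 57 and 8. Apart from the q, these settings count fewer transcripts by construction; 289 of the 304 and 222 of the 249 with such a q were also at 2-fold or more. With a pseudocount of 0.1 FPKM, the count in HT-29 stayed within 1.5 times at 7388, and the others were 6802, 955, 325, 328 and 37. The common RIP minimum gave 109 lncRNA transcripts in CaCo-2 and left the other counts within 1.5 times. With 1 transcript per gene name, counts over all transcripts were 3606, 2694 and 933 and the lncRNA count in both lines 25, since different isoforms then pair. The correlation between lines, 0.52 as reported, was 0.37 with a pseudocount of 0.1, 0.41 with 1 FPKM in both libraries, 0.36 without small RNAs, 0.32 by rank, 0.35 without transcripts at input 0 and 0.37 with 1 transcript per gene name; the cause was not tested. Dropping the FPKM filter or keeping the status OK alone says nothing about stability: a transcript below 1 FPKM in both libraries cannot reach 2-fold with this pseudocount, and all listed transcripts have that status. Of 354 medians of gene lists under other settings, 69 moved by more than 50% of the interquartile range of the list's members, 47 of them upward, and 0 changed sign, which the selection of the tables prevents. Centring, rescaling, counts of lower transcripts and the limma test across lines were not run, since the tables hold part of each library. RBM5-AS1 gave no value under any setting. Depth is unknown, and input values near 0 limit every ratio of a low transcript.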

Other observations

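All tests in this part but the overlap of antisense transcripts were chosen after the result was seen.

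In HT-29, several H/ACA snoRNAs, which guide pseudouridylation in the nucleolus, had RIP values far above the smallest recurring value, or step, for their length: SNORA71A at 221 times, SNORA71C at 157, SNORA31 (ENST00000362607) at 146 and SNORA84 at 96. The step was measured at the length of SNORA84 and interpolated for the others. In the authors' deposited table q was 8.01e-05 for SNORA71A and 0.00185 for SNORA71C, but 0.936 for SNORA31 (ENST00000362607) and 0.667 for SNORA84. A second SNORA31 transcript (ENST00000517242) was at 128 steps, with 3591 against 525 FPKM and q of 8.01e-05 in that table. SNORA71D was at 116 steps, with q of 0.0926 there. In the HT-29 input the same kind of step was found at lengths that include 133 and 135 nucleotides, and SNORA84 was at 10 such steps there. SNORA5A, SNORA71C, SNORA31 (ENST00000517242) and SNORA71A were at 9 to 28 input steps. SNORA66, SNORA13, SCARNA18, SNORA14A and SNORA2A were at 1 input step, and SNORA71D and SNORA14B at 2, so some folds rest on very few steps in input. The 7SL RNA gene RN7SL2 was at 50539 against 32943 FPKM in HT-29, and RN7SL1 at 1906 against 344.

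A first pattern is the set of short RNAs listed at 0 in input. If 1 step is worth 1 sequenced fragment, 89.3% of the 75 such RNAs in HT-29 (95% Wilson interval 80.3 to 94.5) and 98.1% of the 108 in CaCo-2 (93.5 to 99.5) rest on 3 or fewer fragments in the RIP. Some of these count as 1 by construction, since their own value sets the step; without them the shares were 78.4% of 37 (62.8 to 88.6) and 94.4% of 36 (81.9 to 98.5). This is consistent with high FPKM arising from 1 to 3 fragments divided by a very small effective length. The exceptions include U3 (ENST00000516366, 45 steps) and SNORA46 (57 steps) in HT-29. Whether the few fragments reflect binding cannot be judged from 1 library per group.

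A second pattern is the higher level of H/ACA snoRNAs and scaRNAs in the HT-29 RIP, with a median fold of 6.54 where input was above 0. At the 2 lengths where both steps were known, 133 and 135 nucleotides, the FPKM of 1 step differed by at most 1.052-fold. At these lengths the fold therefore comes from the number of steps. A step depends on effective length and depth together, and depth is unknown. The comparison thus cannot decide whether the length model differs between the 2 libraries, and other lengths were not covered. More RNA without a poly(A) tail in the RIP library as a whole would raise other such RNAs as much; Y RNAs, 7SL and 5S rRNA genes lay lower in median log2 ratio by 2.04 over 52 transcripts, against a larger interquartile range of 2.003, which the bound as first written counted against this cause, but 33 of the 52, mostly 7SL copies, had an input below 2 FPKM, and a limit on low inputs was added after the result was seen. Without copies the difference was 1.24 over 5 genes and 1.4 over 46 transcripts of all other classes, both within that range. The class medians with input above 0 were 0.94 for histone transcripts, 1.35 for C/D snoRNAs and 1.64 for snRNA genes, against 2.71. They were 1.15 for mitochondrial tRNAs and 1.47 for 5S rRNA genes. Nearest to 2.71 were RMRP and RPPH1 at 2.31 and Y RNAs at 2.21, each over 2 transcripts. Enrichment with beta-catenin and a shift in library composition cannot be told apart. Members of the other classes that were not higher in the RIP are not listed, and no mock precipitation was analysed here. The interquartile range is the spread of single RNAs and not the error of a difference of medians, so setting the differences against it does not decide the question.

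A further pattern is the number of antisense transcripts among the listed lncRNAs. If reads of the opposite strand had been counted without regard to strand, it was predicted that most antisense transcripts would overlap a listed transcript of another class on the opposite strand. In HT-29 27.8% of 266 did (95% Wilson interval 22.8 to 33.5) and in CaCo-2 30.1% of 376 (25.6 to 34.9), against 3.75% and 5.49% of lincRNAs. These shares lie between the bounds set before the overlap was computed, above 50% for this cause and below 20% against it. The explanation cannot be told apart from antisense transcripts measured on their own strand, since lincRNAs lie apart from genes by definition and the strandedness of the libraries is not given in the sources used here.

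The share of transcripts also listed in the other line, outside small RNAs and above the common RIP minimum, was 14.002% below 2 FPKM in the CaCo-2 RIP and 54.9% at 20 FPKM or more, the latter over 51 transcripts. In HT-29 the shares were 17.0% and 18.1%. Retained-intron transcripts made up 22.7% of the CaCo-2 table and 17.0% of the HT-29 table.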
